A study of Homo sapiens with 4 samples.

How the data were processed

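Total RNA was isolated with a silica column kit from T24T and UMUC3 cells stably carrying an empty vector or a BCUC-1 plasmid, and sequencing libraries were prepared with standard Illumina protocols, per the labels. The 4 groups (T24T vector, T24T BCUC-1, UMUC3 vector, UMUC3 BCUC-1) held 1 library each, and each sample column was assigned to its group by its title. The deposited table gives RPKM for each gene and library, which the authors scaled per kilobase of gene length and per 1000000 assigned reads. It also gives, per the file headers, a Length in bases, of unit "other", which is the exonic length of the gene. Bowtie 0.12.2 is named in the submitters' processing notes. The role of that tool, the genome build and the annotation are not given in the sources used here. How reads that match several places were assigned is therefore not known, and reads of a pseudogene may come from its parent gene.

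The unit was checked on the values. The product of RPKM and length was a whole multiple of 1 step per library for 100% of the genes, within a tolerance of 0.001 reads, so the read counts and depths could be recovered exactly. Reads and fragments cannot be told apart in this way. The depths were 23679229, 23588847, 26497894 and 22730112 assigned reads for T24T vector, T24T BCUC-1, UMUC3 vector and UMUC3 BCUC-1. A gene with 0 reads in a library could have up to 3 reads per library within counting error. Of 32973 listed genes, 22794 symbols are in GENCODE 29, and of the 22720 with a single GENCODE gene 96.6% shared its start or end, so coordinates are given on GRCh38. Spreadsheet date conversion had altered 27 gene names, and 2 symbols were repeated. These genes stayed in the tests but were not named. The counting was not strand-specific. Of 173 genes contained in exons of an opposite-strand gene, 99.4% had reads, with a median level 1.20 times that of the host. Of 53 genes contained in exons of a same-strand gene, 100% had reads, with a median level 0.733 times that of the host. A read in a contained gene could thus count for its host too. The depths are sums over genes, so they can hold such reads more than once.

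The comparisons, tests, gene lists, rule for named genes and a set of other settings were fixed before the data were examined. The effect of BCUC-1 over both lines was tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(RPKM + 1) of genes with at least 1 RPKM in 2 or more libraries. The model held line and treatment and left 1 residual degree of freedom. The test was two-sided at a Benjamini-Hochberg adjusted p of 0.05. The line term of the same model gave T24T against UMUC3. A line by treatment interaction leaves no residual degree of freedom and was not testable.

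Within a line, with 1 library per group, no test across genes was made. A gene counted as different at an absolute log2 change of at least 1 with at least 1 RPKM in a library of the line. The overlap of the lines was set beside the number expected from the sizes of the lists, and the changes of the lines were correlated across genes. Gene list medians were placed among 10000 random lists drawn from 20 expression bins, for lists with at least 5 measured members. There were 31 lists of pathway genes and cell type markers. Reads per 1000000 assigned reads (RPM) were compared between libraries. Their ratios carry exact (Clopper-Pearson) 95% intervals, and levels carry exact Poisson 95% intervals. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

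The named genes were FNDC3B and MMP9, the 10 largest changes each way in a line, the 10 largest each way shared by both lines, genes that were 2-fold higher in one line and 2-fold lower in the other, the 10 largest differences between the lines each way, and up to 4 members of each list by mean change. In the account of the line contrast, list members were instead chosen by their line difference, after the values were seen. Because the planned floor let through short genes with few reads, further rules were added after the data were seen. These were recovered reads with a floor of 1 RPM in a library and 20 reads in the pair (prior count 2), abundant genes with at least 1000 reads in the pair, and removal of the GC trend of each line, taken as the median change in 20 GC bins. GC content was that of the longest GENCODE 29 transcript of the symbol, for the 69.1% of genes that could be matched.

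The other settings fixed in advance were limma-voom on the recovered reads, quantile normalization, no filter, a floor of 5 RPKM, a pseudocount of 0.1, no line block, scaling to equal medians or equal totals, and each line alone. The limma test was tested on simulated data with the real depths and a dispersion of 0.005, in which 200 drawn genes carried known changes. Limma with a trend recovered 87.5% of genes changed 2-fold and 32% of those changed 1.5-fold, with 61 false calls among 15243 unchanged genes, and false calls made up 30.3% of its calls. Limma-voom recovered 95.8% and 52%, with 6 false calls. The simulation gave every gene the same dispersion in both lines and held no GC trend. In the real libraries, genes with at least 10000 reads in the pair had log2 changes with an SD of 0.134 in UMUC3 and 0.058 in T24T. The simulated rates may therefore not hold for the real libraries. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. No level is given for the circular RNA, because gene-level values do not measure it.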

Results

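Transcript levels were measured by RNA sequencing in 2 human bladder cancer cell lines, T24T and UMUC3. Each line had been stably transfected either with an empty vector or with a plasmid for BCUC-1, the circular RNA hsa_circ_0001361, whose host gene is FNDC3B. The stated purpose was to screen for genes downstream of BCUC-1. The 4 groups held 1 library each, so there was no replicate check, and each comparison within a line compares those libraries, not the conditions. The reads assigned to the 32973 listed genes numbered 23679229 in T24T vector, 23588847 in T24T BCUC-1, 26497894 in UMUC3 vector and 22730112 in UMUC3 BCUC-1. Between 26385 and 26808 genes had at least 1 read in a library. Mitochondrial genes took 3.92% of the reads in T24T vector, 3.84% in T24T BCUC-1, 6.33% in UMUC3 vector and 5.30% in UMUC3 BCUC-1. The 95% intervals given below cover counting error only.

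MMP9, a matrix metalloproteinase that degrades type IV collagen and gelatin, was fixed as a gene of interest before the data were examined, together with the host gene FNDC3B. MMP9 was higher in the BCUC-1 library of both lines. In T24T it had 2 reads with vector and 27 with BCUC-1, a ratio of 13.6 (95% interval 3.41 to 118) after scaling to reads per 1000000 assigned reads (RPM). In UMUC3 it had 37 reads with vector and 137 with BCUC-1, a ratio of 4.32 (2.98 to 6.39). In RPM these were 0.0845 (0.0102 to 0.305) and 1.14 (0.754 to 1.67) in T24T, and 1.40 (0.983 to 1.92) and 6.03 (5.06 to 7.13) in UMUC3. MMP9 lies on chromosome 20 from 46008908 to 46016561 on the plus strand. The antisense gene RP11-465L10.10 overlaps it by 430 bases and had 5 and 9 reads in T24T and 50 and 84 in UMUC3, and the counting was not strand-specific. On log2(RPKM + 1), the planned measure, the differences were 0.52 in T24T, below the 2-fold rule, and 1.16 in UMUC3. At 0.0362 to 2.58 RPKM, MMP9 reached the floor of 1 RPKM in 1 library and was therefore outside the test planned over both lines. The planned limma setting with no filter on low values did include MMP9. There 0 of 32973 genes passed, and limma's smallest Benjamini-Hochberg adjusted p was 0.930. With a read floor chosen after the data were seen, limma-voom gave MMP9 a log2 change of 2.46 (SE 0.32), with 2 of 2 lines higher. Its Benjamini-Hochberg adjusted p from limma-voom was 3.85e-10. That fit had 1 residual degree of freedom and took its variance from all genes, so this p does not allow for MMP9 varying more than other genes between cultures.

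**Figure D1:**
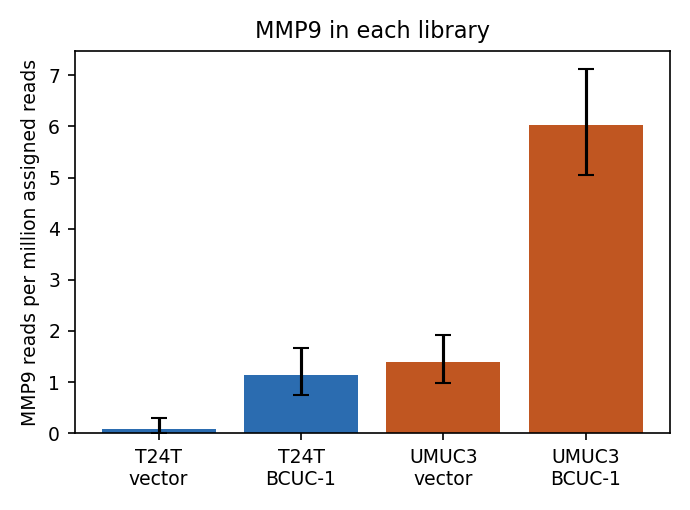
MMP9 level in RPM (vertical axis) in each of the 4 libraries, as bars with 95% Poisson intervals of the read count. The BCUC-1 bars stand at 1.14 in T24T and 6.03 in UMUC3, against 0.0845 and 1.40 with vector.

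FNDC3B, which encodes a membrane protein and whose exons form the circle, had near-equal levels in both libraries of each line. It had 1786 reads with vector and 1689 with BCUC-1 in T24T, a ratio of 0.949 (0.888 to 1.02). In UMUC3 it had 2206 and 1868 reads, a ratio of 0.987 (0.928 to 1.05). FNDC3B spans chromosome 3 from 172039628 to 172401665. Its gene-level value does not measure the circular RNA, so no level of BCUC-1 is given.

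The question posed over both lines was which genes responded to BCUC-1 alike in T24T and UMUC3. Among genes with at least 1000 reads in the pair of each line, and with a minimum set for each library too, the shared differences were small. On the log2 scale the largest shared lower values were at AP000769.1, which lies within the span of MALAT1 (-0.32 in T24T, -0.27 in UMUC3), BMPR2, a bone morphogenetic protein receptor (-0.28, -0.25), SLC39A10, a zinc importer (-0.26, -0.24), and NFAT5, the osmotic stress transcription factor (-0.37, -0.24). ZBTB44 stood at -0.19 and -0.24, and the nuclear noncoding RNA MALAT1 at -0.28 and -0.18. CFAP36, CASD1, PCMTD2 and EXOC6 were lower by similar amounts, with values from -0.24 to -0.16. Among the shared higher values were CH507-513H4.3 (0.27, 0.23), CH507-513H4.5 (0.22, 0.22), RP11-475C16.1 (0.23, 0.19), the pseudogene NPM1P27 (0.19, 0.28), HGH1 (0.19, 0.37), the riboflavin transporter gene SLC52A2 (0.18, 0.20), ACOT7 (0.18, 0.27), RMDN3 (0.18, 0.19) and MAP3K14, the kinase of the noncanonical NF-kB pathway (0.27, 0.17). With the trend on GC content removed, a setting chosen after the data were seen, most of the UMUC3 values were smaller. They were -0.13 for BMPR2, -0.12 for SLC39A10, -0.17 for NFAT5, -0.15 for ZBTB44, -0.11 for MALAT1 and -0.030 for EXOC6, and 0.19 for HGH1, 0.12 for ACOT7, 0.084 for RMDN3, 0.049 for MAP3K14 and 0.016 for SLC52A2. Those of AP000769.1 (-0.34) and NPM1P27 (0.33) were larger.

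None of these passed the planned test. With limma on log2(RPKM + 1) and the line as a block, 0 of 15415 genes passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p, shared by RNU7-75P (log2 change -1.09), SNORD98 (-1.06), MIR6865 (-1.34) and MIR6856 (1.0), was 0.104. At an unadjusted p under 0.05 there were 652 genes. The genes with the smallest p were short noncoding genes with few reads, such as RNU7-75P (12, 5, 7 and 2 reads in T24T vector, T24T BCUC-1, UMUC3 vector and UMUC3 BCUC-1) and SNORD98 (24, 12, 24 and 8 reads). The count depended on the tool and the floor. It was 13 with limma-voom on the recovered reads, 60 at a floor of 5 RPKM, 1 with a pseudocount of 0.1, and 0 with quantile normalization, with no filter, without the line block or with the GC trend removed.

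The limma-voom calls were 3 higher and 10 lower genes, and most followed UMUC3 alone. Here too the variance was taken from all genes. Reads of pseudogenes cannot be told apart here from reads of their parent genes. The pseudogene EEF1A1P13 had a log2 change of 0.65 (SE 0.11) with values of 0.053 in T24T and 1.10 in UMUC3, and AC009299.5 had 0.85 (SE 0.16) with 0.015 and 1.24. YBX1P1 had 0.40 with 0.034 and 0.73. BIRC3, an apoptosis inhibitor induced by NF-kB, had -0.40 (SE 0.082) with -0.037 and -0.55. The mitochondrial genes MT-RNR2, MT-TK, MT-TG, MT-ND3 and MT-ND4L were lower, with combined values from -0.42 to -0.24. The pseudogenes MTND2P28 (-0.31) and RPL6P27 (-0.33) were lower too. NFAT5 (-0.33, SE 0.071) and RP11-311C24.1 (-0.55, SE 0.12) were lower in both lines. RP11-311C24.1 lies within the span of NFAT5 on the same strand, at 20.6 against 20.8 RPKM in T24T vector. Both calls may therefore rest on shared reads. Of the 60 calls at 5 RPKM, 44 were genes shorter than 200 bases.

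In T24T, the abundant genes (at least 1000 reads in the pair) differed little between the BCUC-1 and vector libraries. Among the highest log2 differences were those at the metallothionein MT1E (0.50, 1084 against 1542 reads, ratio 1.43 with interval 1.32 to 1.54), the transcription factor FOXD1 (0.28), MAP3K14 (0.27), CYR61, a matricellular growth factor (0.27), the chemokine CXCL1 (0.25), the AP-1 subunit JUN (0.25), FRMD6 (0.25) and OCIAD2 (0.25). Among the lowest were RP11-311C24.1 (-0.53), LINC00342 (-0.48), the paraspeckle RNA NEAT1 (-0.43, 16678 against 12215 reads, ratio 0.735, 0.718 to 0.753), AC159540.1 (-0.38), NFAT5 (-0.37), the transcription regulator ID4 (-0.37), the keratinocyte kinase RIPK4 (-0.37) and PABPC1L (-0.36). None of the 7678 abundant genes differed 1.5-fold or more, and their log2 differences had an SD of 0.077.

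Among less abundant T24T genes with at least 1 RPM in a library and 20 reads in the pair, MMP9 had the largest difference. It was followed by HIST2H2BC (11 against 33 reads), the calcium-binding protein gene CABP7 (17 against 48), LINC00702 (11 against 32), RP11-114M5.1 (12 against 33) and KRTAP2-3 (18 against 48). Among the lowest were RP5-1112D6.4 (27 against 6 reads), RP11-690I21.2 (26 against 6), GRAP2 (24 against 7), the neuropeptide gene NPFF (29 against 10), the uroplakin gene UPK2 (25 against 9) and the interleukin gene IL23A (25 against 9). That rule, added after the data were seen, counted 14 genes at least 2-fold higher and 42 lower of 16084. By the planned rule of size on log2(RPKM + 1), 43 genes were at least 2-fold higher and 47 lower of 14946. Of these 90 genes, 86 were shorter than 200 bases and 84 had fewer than 20 reads in the pair, with a median of 3 reads. Among the largest were RNU6-762P (0 against 5 reads), MIR4489 (0 against 3) and MIR4324 (4 against 0), whose ratios had intervals that included 1, and SNORD116-28 (6 against 0 reads), whose ratio had an upper 95% bound of 0.853. Genes of at least 500 bases with a mean level under 0.1 RPKM had, summed, 0.872 times the RPM with BCUC-1 that they had with vector (0.854 to 0.891). In UMUC3 the same genes had a ratio of 1.06 (1.03 to 1.08).

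In UMUC3, the highest abundant genes with BCUC-1 were the pseudogenes EEF1A1P13 (log2 difference 1.10, 615 against 1164 reads, ratio 2.21, 2.0 to 2.44), YBX1P1 (0.73) and RPS23P8 (0.66), the secreted serine protease HTRA1 (0.51, ratio 1.45, 1.33 to 1.58), PRKCDBP (0.50), the transcription factor SOX12 (0.48), the linker histone H1FX (0.48) and CHCHD10, a mitochondrial intermembrane space protein (0.47). With the GC trend removed the values were 1.06 at EEF1A1P13, 0.62 at YBX1P1, 0.68 at RPS23P8, 0.39 at HTRA1, 0.33 at SOX12, 0.30 at H1FX and 0.29 at CHCHD10. Among the lowest were RP11-56B16.4 (-0.71), RPL39P5 (-0.64), MT-TG (-0.63), MT-TK (-0.61), MTND2P28 (-0.59), RPL6P27 (-0.59), MT-ND3 (-0.55) and BIRC3 (-0.55, 6811 against 3939 reads, ratio 0.674, 0.648 to 0.701, and -0.39 with the GC trend removed). CTGF, a growth factor of the same family as CYR61, stood at -0.44 and was named after its value was seen. Of the mitochondrial genes, 35 of 35 were lower in UMUC3 BCUC-1, from -0.63 to -0.083 with a median of -0.31. In T24T 31 of 35 were lower with a median of -0.035, and 23 of 35 when the libraries were scaled to equal medians. Of 7463 abundant UMUC3 genes, 1 differed at least 2-fold and 9 differed over 1.5-fold, and the SD was 0.14. The reads of the pseudogenes named here may come in part from their parent genes.

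Among less abundant UMUC3 genes, MMP9 was again the largest by recovered reads. HMGB1P20 (15 against 57 reads), RP11-586D5.3 (9 against 33), CTD-2561B21.4 (9 against 32), SERPINB10, a leukocyte serpin gene (8 against 24), NPFF (8 against 24) and the zinc finger gene ZNF425 (11 against 30) were among the next. Among the lowest were RP5-1073O3.2 (39 against 9 reads), RNU6-1016P (38 against 9), LINC01111 (32 against 9) and the microRNA gene MIR221 (47 against 16). This rule counted 48 genes at least 2-fold higher and 28 lower of 15686. The planned rule of size counted 55 higher and 53 lower of 14347, of which 99 were shorter than 200 bases and 90 had fewer than 20 reads. The UMUC3 differences also followed base composition. The median log2 difference went from -0.13 to 0.17 between the lowest and the highest of 10 equal groups of genes ordered by GC content (Spearman rho 0.568 across 11601 genes, which are not independent replicates). The T24T differences had a rho of 0.0232.

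**Figure D2:**
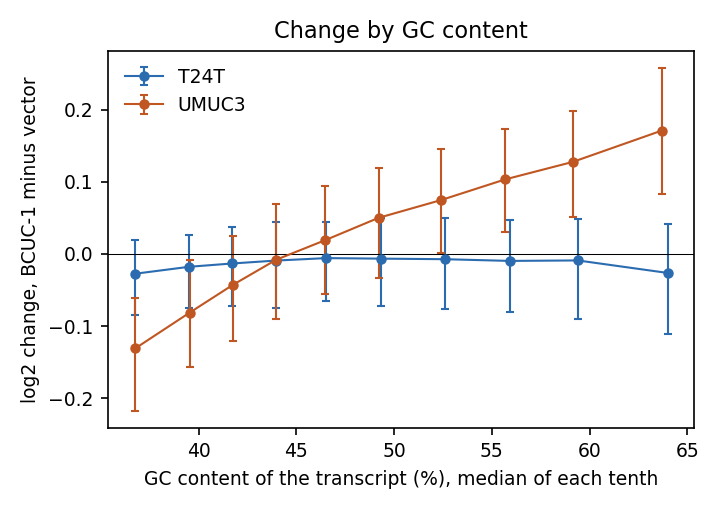
Median log2 change, BCUC-1 minus vector (vertical axis), in 10 equal groups of genes ordered by GC content of the transcript in percent (horizontal axis), for each line, with bars from the lower to the upper quartile of the genes. The UMUC3 medians run from -0.13 to 0.17, and the T24T medians stay between -0.027 and -0.0058.

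Whether both lines responded alike was also asked gene by gene. Across 13049 genes above 1 RPKM in both lines, the log2 differences of T24T and UMUC3 had a Pearson r of -0.00093 and a Spearman rho of -0.021, and 49.4% shared a sign. MIR6865 (-1.56 in T24T, -1.11 in UMUC3) and RNU7-75P (-1.05, -1.12) were at least 2-fold lower in both lines, against 0.0472 genes expected from the sizes of the lists, and both had at most 12 reads in a library. No gene was at least 2-fold higher in both lines under that floor, against 0.0404 expected. By recovered reads, 1 gene of 14499 was at least 2-fold higher in both lines, MMP9, against 0.0095 expected. In opposite directions there were 4 genes above 1 RPKM and 1 by recovered reads, NPFF. The expected numbers assume that the lists of the lines are independent and that each gene is equally likely to pass. Of the genes past the planned rule, 84 of 90 in T24T and 90 of 108 in UMUC3 had fewer than 20 reads in the pair. By recovered reads the spread was largest from 20 to 100 reads in the pair, with an SD of 0.45 in T24T and 0.48 in UMUC3. Genes with few reads can pass in both lines by counting error, so no excess can be read from the expected numbers.

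**Figure D3:**
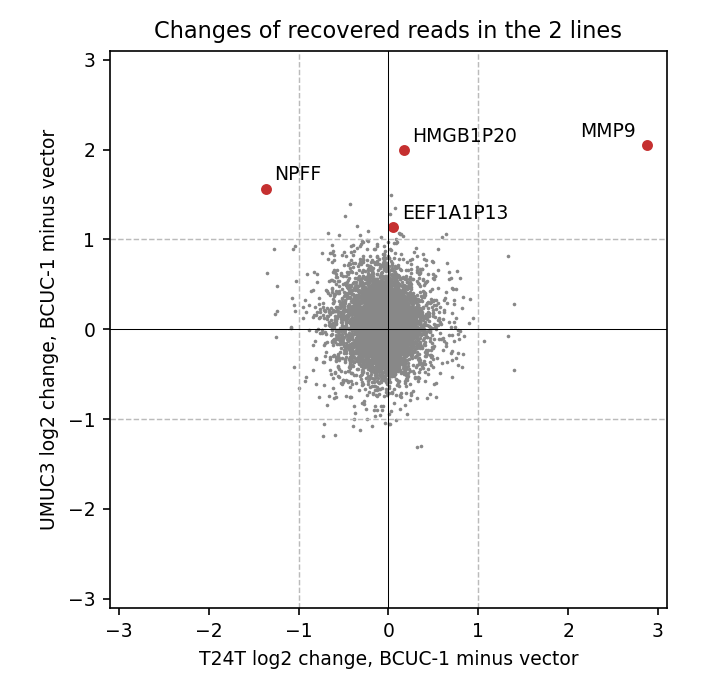
Log2 change of recovered reads, BCUC-1 minus vector, in T24T (horizontal axis) and UMUC3 (vertical axis), with 1 point per gene and dashed lines at a 2-fold change. MMP9, at 2.87 and 2.05, is the single gene past the lines in both cell lines in the same direction.

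The fixed gene lists were next compared with random lists of the same size and expression level. In T24T the histone list was low, with a median log2 difference of -0.15 (percentile 0.230) and 7 of 9 members lower, among them HIST2H2AA3 (-0.42), HIST1H2BC (-0.25) and HIST2H2BE (-0.23). With no floor it was inside the random range (median -0.077, percentile 6.25), and at 5 RPKM 4 members were too few for a percentile. In UMUC3 its median had no fixed sign, at 0.076 (4 higher and 3 lower), -0.040 with the GC trend removed and -0.016 by recovered reads. The list of NF-kB and inflammatory cytokine genes had a median of 0.054 (percentile 98.0) with 6 members higher, such as CXCL1 (0.25), CXCL2 (0.15) and RELB (0.14), and 4 lower, and was inside the range with no floor (percentile 95.4) and at 5 RPKM (percentile 78.9). In UMUC3 it stood at 0.033 (8 higher and 6 lower), and at -0.037 (4 and 10) with the GC trend removed. The MAPK feedback list had 0.051 (percentile 98.1) with 11 of 13 members higher, among them DUSP5 (0.11) and EPHA2 (0.077). In UMUC3 it stood at -0.042 (6 higher and 7 lower), 0.030 (9 and 4) with equal totals and -0.064 (4 and 9) with the GC trend removed. In UMUC3 the hypoxia and glycolysis list had a median of 0.12 (percentile 99.4) with 17 of 21 members higher, including the glycolytic enzymes GAPDH (0.29), PKM (0.27), PGK1 (0.19) and ENO1 (0.092). With the GC trend removed its median was 0.070 (percentile 99.8). In T24T it was inside the range, at 0.029 (percentile 92.3) with 13 higher and 7 lower. Averaged over the lines, this list stood at 0.075 (percentile 99.8). The mesenchymal marker list stood at 0.078 (percentile 97.6, 7 higher and 2 lower), but it was inside the range in each line alone (percentiles 78.5 and 52.5) and, averaged, under each other setting except the floor of 5 RPKM.

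The list of matrix metalloproteinases and their inhibitors had a median of -0.013 in T24T (percentile 56.9) and of 0.12 in UMUC3 , at the upper edge of the random range. By recovered reads, a setting chosen after the data were seen, it was above the range in both lines, with medians of 0.049 (percentile 98.8) and 0.15 (percentile 98.4). In UMUC3 it was also above it with a pseudocount of 0.1 (98.7) and equal medians (98.1), and inside it with equal totals (93.6), no floor (80.4), 5 RPKM (16.4) and the GC trend removed (92.9). Its members beside MMP9 included MMP15 (-0.12 and 0.43), MMP2 (-0.034 and 0.30) and MMP16 (-0.12 and -0.11). The cell cycle list (0.029 and 0.049), the p53 target list (-0.061 and 0.077), the interferon-stimulated list (-0.068 and 0.050) and the list of circular RNA and RNA sensing factors (-0.040 and 0.0032) lay inside the random range. Lists outside the central 95% numbered 3 of 26 in T24T and 1 of 26 in UMUC3, against 1.3 expected by chance in each. Over the other settings they numbered from 1 to 6 in T24T and 1 to 3 in UMUC3. The expected number treats the members of a list as unrelated, while genes regulated together can move together between single cultures. In the limma test over both lines, 0 members of the 31 lists passed over all genes and 0 adjusted over the list alone. LAMB3, SKIL, IDI1, CYC1 and HIST1H2BC had an unadjusted p under 0.05, and limma-voom called BIRC3.

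**Figure D4:**
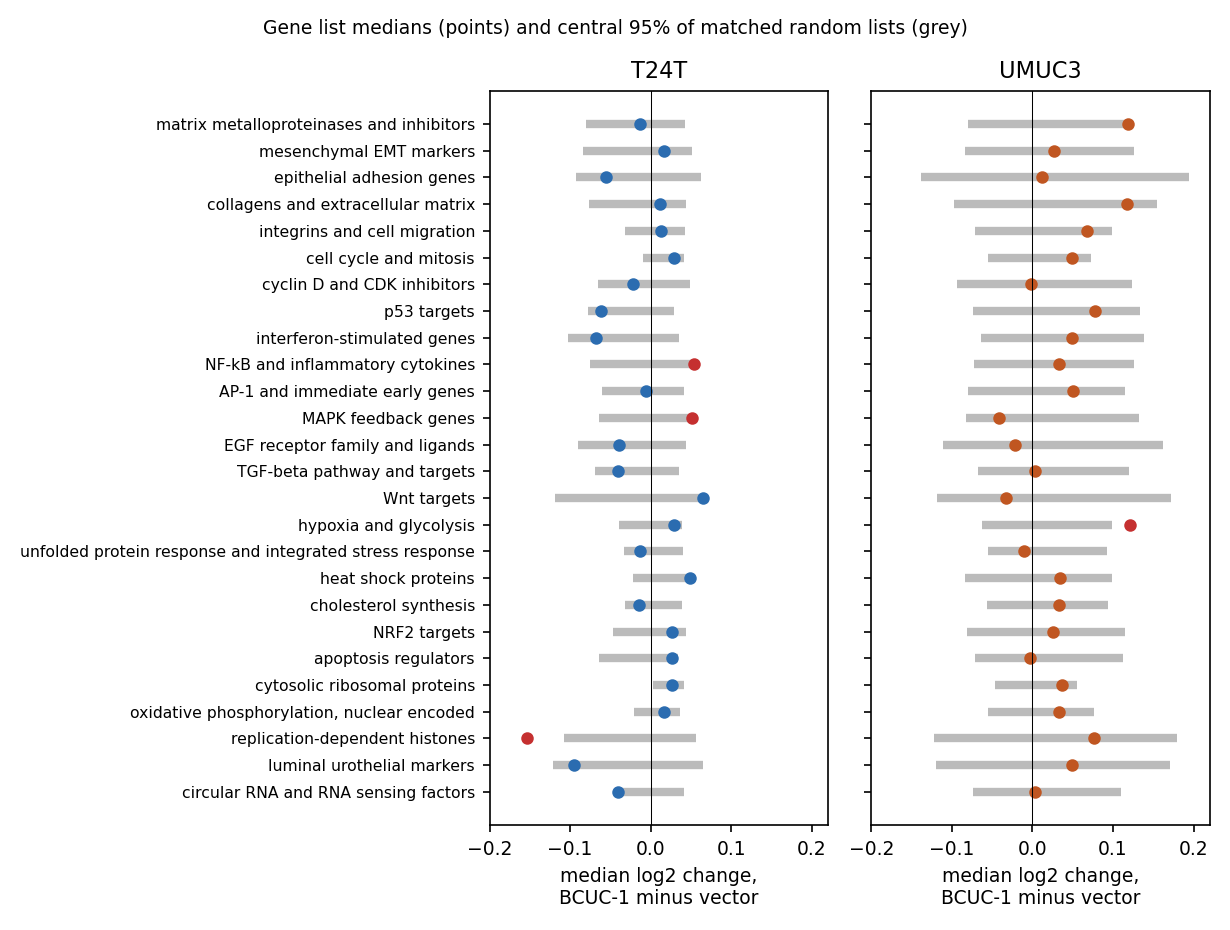
Median log2 change, BCUC-1 minus vector (horizontal axis), of each fixed gene list (points) in T24T and in UMUC3, with grey bars for the central 95% of random lists of matched size and level. Red points lie outside the bars, which are the NF-kB (0.054), MAPK feedback (0.051) and histone (-0.15) lists in T24T and the hypoxia and glycolysis list (0.12) in UMUC3.

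The baseline differences between the lines were compared to place those between BCUC-1 and vector. On the log2 scale T24T was higher in the retinaldehyde dehydrogenase ALDH1A3 (7.06, SE 0.082), the peptidylarginine deiminases PADI2 (6.97, SE 0.081) and PADI3 (6.50, SE 0.081), ARHGEF35 (6.05), the stathmin family gene STMN3 (5.96), the growth factor midkine, MDK (5.86), and the metallothionein MT1E (5.65), and in RP11-66B24.8, RP11-66B24.4 and AC009133.22 (5.54 to 5.66). UMUC3 was higher in CTD-2184D3.5 (-6.55 for T24T minus UMUC3, SE 0.15), the decoy receptor IL13RA2 (-6.52, SE 0.12), LINC01029 (-6.02), the matricellular protein SPARC (-5.60, SE 0.084), ALDH1A1 (-5.21), HTATIP2 (-5.03), CTB-60B18.15 (-4.91) and the cancer-testis antigens MAGEA6 (-5.14), MAGEA4 (-5.10) and BAGE5 (-5.13). All 20 genes passed limma's test with Benjamini-Hochberg adjusted p from 2.36e-07 to 8.12e-07. In all, 10847 of 15415 genes (70.4%) passed an adjusted p of 0.05 in limma after Benjamini-Hochberg correction, 6289 higher in T24T and 4558 higher in UMUC3. With quantile normalization the split was near even, 5436 against 5316. At least 4-fold differences numbered 358 and 291. The pair of libraries of a line differed in plasmid and came from single cultures. The error of this test is how unlike the BCUC-1 minus vector differences of T24T and UMUC3 were. It does not measure the variation between cultures of a line.

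Protease and mesenchymal genes were mostly higher in UMUC3. Of the 16 tested matrix metalloproteinase and inhibitor genes, 13 were higher in UMUC3 and 3 in T24T, and 16 passed adjusted over the list alone. The urokinase gene PLAU (-2.51), MMP2 (-2.42) and MMP1 (-2.38) were higher in UMUC3, and SERPINE2 (1.42) in T24T. Of 14 mesenchymal markers, 9 were higher in UMUC3, such as SPARC, AXL (-1.98) and VIM (-1.55), and 5 in T24T, with 14 adjusted over the list alone. The NF-kB and cytokine list had 10 of 14 genes higher in UMUC3, including BIRC3 (-2.30) and CSF1 (-2.15), and 3 higher in T24T, including LIF (2.45) and CXCL1 (1.76), with 13 adjusted over the list alone. Of 15 AP-1 and immediate early genes, 10 were higher in UMUC3, such as CTGF (-2.79) and JUN (-2.62), and 14 passed adjusted over the list alone. Cytosolic ribosomal protein genes were higher in UMUC3 for 25 of 40, such as RPL4 (-1.27) and RPS3 (-1.20), with 26 adjusted over the list alone. NRF2 targets were higher in UMUC3 for 9 of 15, such as GCLM (-1.17), with 13 adjusted over the list alone.

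Epithelial genes, genes of the EGF receptor family and its ligands, and sterol synthesis genes were mostly higher in T24T. Over all 15415 genes tested, 6289 were higher in T24T and 4558 in UMUC3. Of 12 genes on the list of EGF receptor family genes and ligands, 9 were higher in T24T, including the ligands AREG (5.24) and EREG (1.89) and the receptor EGFR (1.58), and 3 in UMUC3, including HBEGF (-2.34), with 12 adjusted over the list alone. Of 7 luminal urothelial markers tested, from 19 listed, 5 were higher in T24T, with KRT8 at 3.31 and KRT7 at 2.75, and 1 in UMUC3. Of 7 epithelial adhesion genes tested, from 17 listed, 4 were higher in T24T, including CLDN1 (4.68) and DSP (4.23), and 2 in UMUC3. In the luminal and in the epithelial list, 6 genes passed adjusted over the list alone. The 2 basal urothelial markers tested, from 9 listed, were higher in T24T too. Collagen and matrix genes were higher in T24T for 9 of 13, led by THBS1 (5.0), with 11 adjusted over the list alone. The cholesterol synthesis list had 16 of 24 genes higher in T24T, such as STARD4 (1.91), MVD (1.53) and HMGCS1 (1.47), and 2 higher in UMUC3, with 18 adjusted over the list alone. Histone genes were higher in T24T for 8 of 9, such as HIST1H1C (1.76), with 8 adjusted over the list alone. The list of circular RNA and RNA sensing factors had 10 of 17 higher in T24T, including IFIH1 (0.88), and 2 in UMUC3, including MBNL1 (-0.45), with 13 adjusted over the list alone.

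Markers of other cell types were nearly absent above the floor. CD68, a lysosomal protein used as a macrophage marker, was the single leukocyte marker tested (-3.92, higher in UMUC3). ENG (-0.54) stood alone for endothelium, ACTA2 (-0.83) for fibroblasts and smooth muscle, and SERPINA1 (1.16) for hepatocytes. The BCUC-1 minus vector differences of these 4 genes ranged from -0.20 to 0.18 where they were above the floor.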

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

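The tests of the MMP9 and GC patterns were chosen only after those results were seen, as were the recovered-read and abundant-gene rules behind the opposite differences.

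Some genes differed in opposite directions in the 2 lines, and none of these differences between lines was tested. Above 1 RPKM, 4 genes were at least 2-fold higher in one line and at least 2-fold lower in the other: MIR6763 and MIR6730, higher in UMUC3, and MIR4641 and SNORD73B, higher in T24T, none with more than 5 reads in a library. By recovered reads, the neuropeptide gene NPFF had a log2 difference of -1.37 in T24T (29 against 10 reads) and 1.57 in UMUC3 (8 against 24 reads). Among abundant genes, PABPC1L stood at -0.36 in T24T and 0.27 in UMUC3, the laminin gene LAMB2 at -0.25 and 0.35, and CXCL1 at 0.25 and -0.28.

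MMP9 was higher with BCUC-1 in both lines. Counting error of independent reads is argued against. In 0 of 1000 redraws of the reads without any change did some gene reach the smaller MMP9 difference (2.05 on the log2 scale) in both lines. The largest value reached was 1.30. The redraws treat each read as an independent molecule, so repeated reads of few molecules were not tested and stay open. The T24T and UMUC3 changes were also re-paired among genes of like read number. In 13 of 10000 re-pairings some gene reached the smaller MMP9 difference in both lines. Re-pairing treats those genes as equally variable between cultures. Taking every read of the antisense gene RP11-465L10.10 off the BCUC-1 libraries alone left ratios of 9.03 (2.16 to 80.3) in T24T and 1.67 (1.08 to 2.61) in UMUC3, both with intervals above 1. With 1 library per line and treatment, an effect of BCUC-1 cannot be told apart from MMP9 being more variable than such genes between single cultures, so both stay open.

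The UMUC3 differences followed GC content. A GC-dependent difference between the UMUC3 libraries is a candidate explanation. The slope on GC was above 0 in coding genes (0.11 per 10 GC points on the log2 scale), in lincRNA and antisense genes (0.057) and in pseudogenes (0.066). The smallest lower bound was 0.029, while the largest T24T slope was 0.013. The intervals of the lines were apart in coding genes (T24T upper bound 0.0023, UMUC3 lower bound 0.103). They overlapped in lincRNA and antisense genes (0.037 and 0.029) and in pseudogenes (0.037 and 0.032). Gene length is argued against, since the rank correlation with GC was 0.571 with length held fixed. A response shared by both lines is argued against too, since the T24T correlation was 0.0232. A response to BCUC-1 in UMUC3 alone was not tested and stays open, as treatment and library are the same in that line.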

How the results depend on the processing

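The read-floor and GC alternatives were chosen only after the results were seen, and the others were planned. Of the values that answer a comparison, 40 stayed within the bounds set and 19 moved. FNDC3B in UMUC3 went from -0.016 to 0.050 with equal totals and 0.014 with the GC trend removed, within its counting interval. Genes past the threshold in limma over both lines were 0 in the main test, 13 with limma-voom, 60 at a floor of 5 RPKM, 1 with a pseudocount of 0.1 and 12 with limma-voom at the read floor. The count for T24T against UMUC3 was 6780 of 8830 at 5 RPKM, where fewer genes were tested, and from 9505 to 12203 under the other settings. Genes at least 2-fold different in T24T went from 90 to 254 with a pseudocount of 0.1, 7 at 5 RPKM and 56 by recovered reads, and in UMUC3 from 108 to 280 and 18 with the first 2 of these. Genes different the same way in both lines went from 2 to 19 with a pseudocount of 0.1, 0 at 5 RPKM and 1 by recovered reads. The Pearson correlation of the lines stayed between -0.034 and 0.0065 and the Spearman correlation between -0.067 and 0.012. Lists outside the random range over both lines went from 2 to 1 with a pseudocount of 0.1, equal medians or equal totals, and to 1 in UMUC3 alone. Of the 40 genes named by size in either line, 4 were shared with the list at 5 RPKM and 3 with that by recovered reads. The log2 difference of MMP9 went from 0.52 to 2.12 with a pseudocount of 0.1 and 2.87 by recovered reads in T24T, and from 1.16 to 1.94 and 2.05 in UMUC3. By construction a smaller pseudocount enlarges size differences at low levels and a stricter floor leaves fewer genes to count by size. For the limma counts over both lines and the other moves the cause was not tested. Leaving out the pair of a line left no residual degree of freedom, so those differences stand as values with no test. The count-based tools planned for a table of counts, edgeR, DESeq2 and RLE size factors, were not run. The plan followed the deposited unit, which is RPKM, although the reads could be recovered. Limma-voom was run on the recovered reads. The counts by size rested on few reads: the median was 3 reads in the pair over all T24T genes at least 2-fold different and 4 in UMUC3. Of these genes, 86 of 90 in T24T and 99 of 108 in UMUC3 were shorter than 200 bases. An effect of depth on the counts was not tested.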

Other observations

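The test on the listed YAP and TEAD targets was written before their values were examined; the GC check on it was added after the first percentiles had been seen but before its own value, and the genes in the first paragraph were chosen after their values were seen.

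The differences between lines in this paragraph were not tested. NEAT1 had a ratio of 0.735 (0.718 to 0.753) in T24T and 0.953 (0.941 to 0.965) in UMUC3, the separately listed NEAT1_1 had 0.733 and 1.10, and MALAT1 had 0.819 (0.799 to 0.839) and 0.884 (0.864 to 0.904). The metallothionein MT2A, a zinc- and stress-responsive gene, stood at 0.22 in T24T (9853 against 11413 reads) and -0.21 in UMUC3 (22498 against 16720 reads). Genes of at least 500 bases with a mean level from 0.1 to 1 RPKM had, summed, a ratio of 0.921 in T24T and 1.05 in UMUC3. The spread between the libraries of a pair exceeded counting error most in UMUC3, with a mean chi-square per gene of 75.5 at 10000 or more reads against 10.5 in T24T.

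The values of CTGF and CYR61, among others, prompted a hypothesis. Both are classic targets of the growth-control factors YAP and TEAD. CTGF and CYR61 were lower in UMUC3 BCUC-1 (-0.44 and -0.18). In T24T BCUC-1 CYR61 was higher (0.27), while CTGF differed little (0.061, 632 against 659 reads). An 18-gene list of other targets, written from general knowledge without CTGF, CYR61 and AXL, was therefore tested, and it was the only list tried in this way. In T24T the median of 15 measured members was 0.11, with 12 higher and 3 lower, at percentile 100 of the matched random lists, whose central 95% ran from -0.071 to 0.040. NT5E (0.21), GADD45A (0.20) and ANKRD1 (0.27) were among the higher members. In UMUC3 the median was -0.081, with 4 higher and 11 lower, at percentile 2.0, where the central 95% ran from -0.078 to 0.12. ANKRD1 (-0.48), IGFBP3 (-0.31) and CRIM1 (-0.18) were among the lower members. With the GC trend of UMUC3 removed the percentile was 1.49, which argues against GC content as the source, and with equal totals the UMUC3 median was -0.011 with 7 higher and 8 lower. These values are consistent with YAP and TEAD output that may have differed in opposite directions between the BCUC-1 and vector cultures of the 2 lines. Members of the random lists were drawn independently of each other. Genes regulated together can move together between any 2 cultures, so these percentiles do not measure how rare such a shift is. With 1 library per group, a difference in culture density, which is known to act on YAP, was not tested and stays open beside BCUC-1.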
